A study of Homo sapiens with 8 samples.

How the data were processed

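RNA was measured in 8 libraries of HMEC-1, a human dermal microvascular endothelial cell line immortalised with a viral large T antigen. Per the labels, 3 libraries came from cells kept in weightlessness on the International Space Station (space_microg), 2 from cells flown in the same incubator but spun in its centrifuge at 1 g (space_1g), and 3 from cells kept in a facility on the ground. The labels do not say whether replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which could be technical. Libraries were made from total RNA with a stranded kit and depletion of ribosomal RNA, per the labels' protocols, so transcripts without a poly(A) tail, such as most histone mRNAs, stay in.

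The deposited values are normalised signal per gene, called CPM per the labels, which are read counts scaled to library size. CASAVA 1.8.2, FastQC, STAR 2.5.3, featureCounts and edgeR, with the builds hg38 and GRCh38, are named in the submitters' processing notes without their roles. The setting used for strand is not given in the sources used here. In each library the deposited values were whole multiples of what 1 read is worth, between 0.0285 and 0.0398 CPM, within a tolerance of 1e-06 read for 100% of values. Scaling factors computed with edgeR's TMM method from these recovered reads equalled those in the deposited columns, with differences of at most 7.77e-16. The columns therefore sum to between 966156 and 1061177 rather than to 1 common total. All 16153 genes in the table had a plain-total CPM above 1 in at least 2 libraries, so genes below that level are not analysed here. Genes of the mitochondrial genome, 0 in the table, are not analysed here either.

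Library depth was 24248964 to 35388757 reads in the listed genes. The 10 most abundant genes took 3.99% to 4.82% of the reads of a library. At this depth a count of 0 allows up to 3 reads, which is 0.0855 to 0.12 CPM, a limit that covers counting error only. Within each group, pairs of libraries differed far beyond counting noise, with a chi-square per degree of freedom of 19.5 to 205, so no library was treated as a duplicate.

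The values were analysed as log2(CPM + 1) with a filter of at least 1 CPM in at least 2 libraries, which kept 16103 genes and left out 50. A fold change is on this log2(CPM + 1) scale and understates the change of low genes. The test was limma 3.58.1 (lmFit, eBayes with a mean trend) in R 4.3.3, two-sided, with all 8 libraries in one fit and no covariates, and Benjamini-Hochberg adjustment at 0.05. The test had been planned for CPM and was kept for the scaled CPM found in the table. The comparisons were space_microg against ground, space_1g against ground, and space_microg against space_1g, followed by the joint direction of the last pair and the overlap of both flight groups. Of 50 gene lists written before the data were examined, 47 had at least 5 measured members and were tested with camera at a preset correlation of 0.01; leukocyte markers with 2 members, erythroid and platelet markers with 1 and the mitochondrial genome with 0 were not tested. Camera with an estimated correlation and fry were run beside it.

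Named genes were chosen by a rule fixed before the data were examined: the largest changes per direction past the threshold, or, where none passed, the 5 genes per direction with the smallest unadjusted p, in both cases with a mean of at least 5 CPM and groups that do not overlap. For a described list up to 4 members with the smallest p were taken, and for the joint directions the 5 genes per class with the largest smaller change. Not every gene that the rule chose is named in the text. Other genes named in the text were chosen after their values were seen and are said to be so. Gene positions are those of GENCODE v29 on GRCh38, in which 13895 of the 16153 symbols were found. Symbols shared by near-identical copies, as for ribosomal proteins and histones, are uncertain where reads could be split between copies.

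The steps were tested on simulated data before use. In simulated counts, 5, 6 and 7 genes without a planted change were called in the comparisons in the order given above. With fold changes planted into the real libraries, limma recovered 82%, 84% and 76% of 4-fold changes and 34%, 12% and 6% of 2-fold changes. Changes of 1.5-, 2-, 4- and 8-fold were planted together, in 50 genes each, which eases the adjusted threshold. With fewer true changes recovery would be lower, so these rates do not exclude 4-fold changes where 0 genes were called. Alternatives planned before the data were examined were pseudocounts of 0.25 and 4, no filter or a filter of 5 CPM, median-of-ratios and quantile scaling, only the 2 groups of a comparison, an added limit of 1 on the log2 fold change, limma without the trend, array weights, the replicate number as a block, and each library left out in turn. Leaving out a space_1g library leaves that group with 1, which is then assumed to vary like the other groups. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, 1 surrogate variable from sva 3.50.0, removal of each library's trend on GC content and transcript length, and a fit without space_1g replicate 1 and ground replicate 3.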

Results

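The data were 8 RNA-seq libraries of HMEC-1 cells: 3 from weightlessness in orbit (space_microg), 2 from the centrifuge at 1 g in orbit (space_1g) and 3 from the ground. In the listed genes, space_microg replicates 1 to 3 held 35388757, 33331416 and 30481131 reads. The space_1g replicates 1 and 2 held 30929975 and 25893168 reads, and ground replicates 1 to 3 held 27183626, 24248964 and 34625881. Means below are scaled CPM ± SD with n = 3 for space_microg and ground and n = 2 for space_1g. Changes of genes are log2 differences ± SE from limma, and changes of lists are the median of their members.

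The widest difference between libraries did not follow the groups. The first principal component, with 61.9% of the variance, set space_1g replicate 1 (score 60.7) and ground replicate 3 (score 64.7) apart from the other 6, of which space_microg replicate 1 lay at 1.51 and the rest between -31.1 and -20.7. Genes induced by p53, the transcription factor that answers DNA damage, had mean scores of 1.05 and 0.88 in these libraries, against -0.75 to 0.16 in the others. Genes induced by interferon, the signal of antiviral defence, had scores of 1.54 and 1.79, with 0.60 in space_microg replicate 1 and -1.25 to -0.31 in the remaining 5. Core histone genes, used when DNA is copied, had scores of -1.72 and -0.85 against 0.04 to 1.16, and genes of mitosis -0.91 and -0.58 against 0.09 to 0.32.

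**Figure D1:**
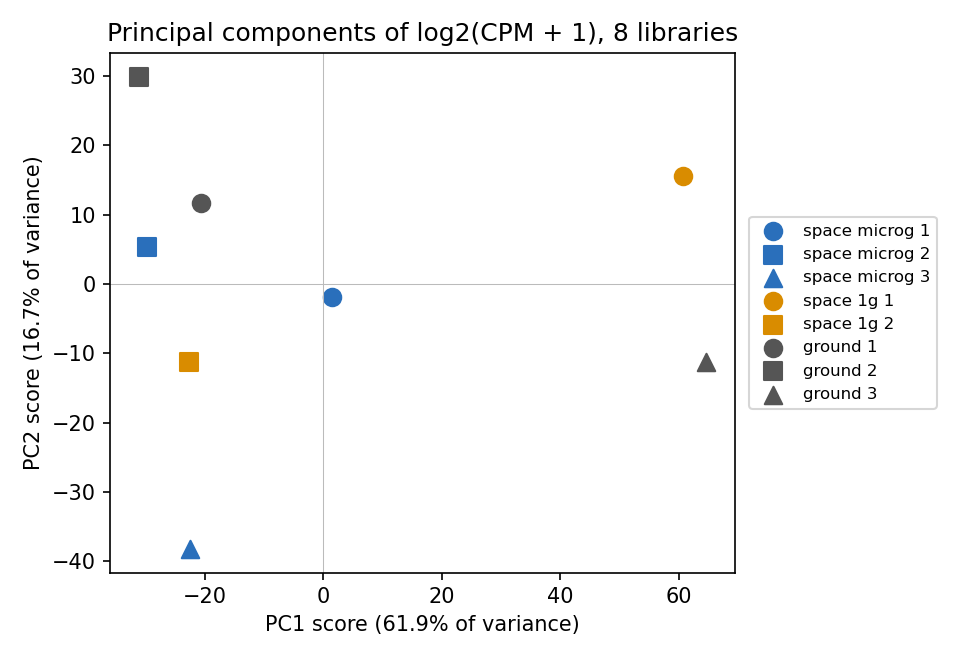
Scores of the 8 libraries on the first and second principal components of log2(CPM + 1), with the colour giving the group and the marker the replicate (circle 1, square 2, triangle 3). Space_1g replicate 1 and ground replicate 3 lie at 60.7 and 64.7 on the first component, and the other libraries at 1.51 or below.

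**Figure D2:**
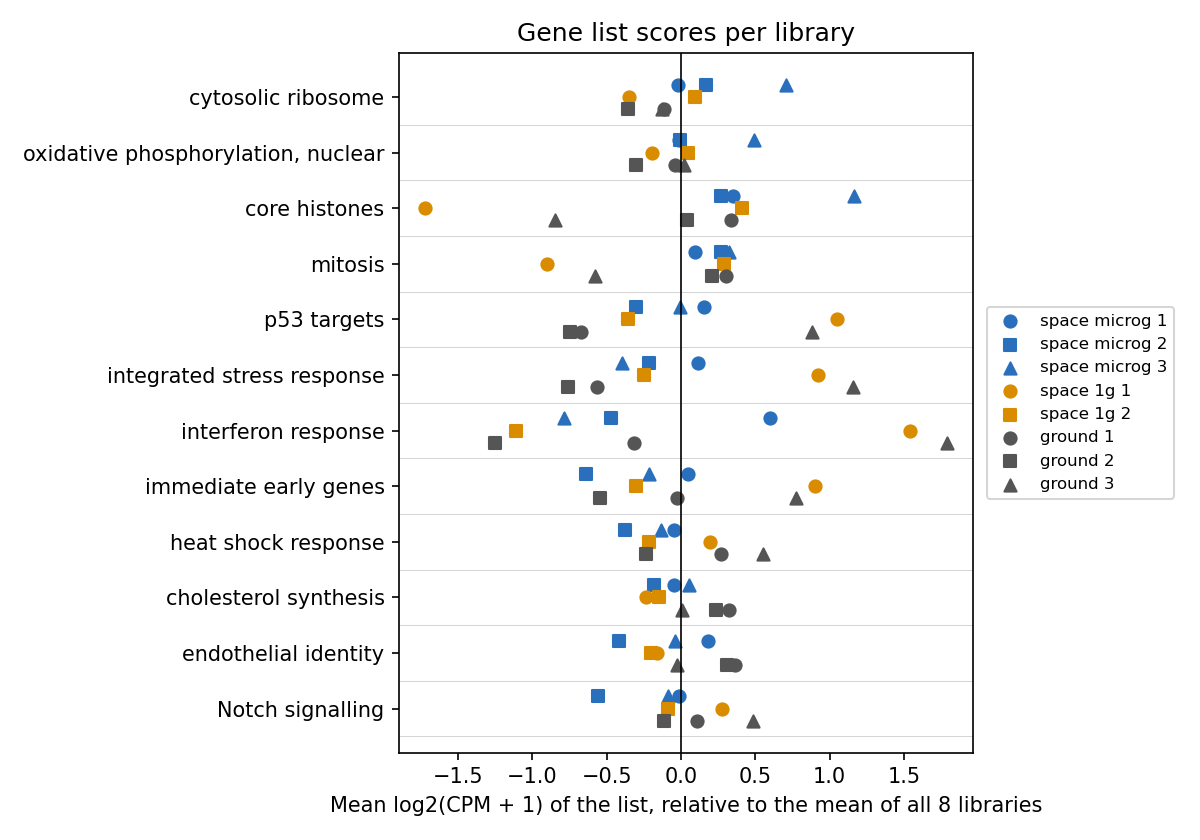
Mean log2(CPM + 1) of gene lists in each library, relative to the mean of all 8 libraries, with the colour giving the group and the marker the replicate (circle 1, square 2, triangle 3). The p53 scores of space_1g replicate 1 and ground replicate 3 are 1.05 and 0.88, and no other library exceeds 0.16.

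Space_microg against ground asks what flight without artificial gravity does, with weightlessness, radiation and all other conditions of flight together. RBM3, an RNA-binding protein induced by mild cold, had 354 ± 56.8 CPM in space_microg and 109 ± 31.2 on the ground, higher by 1.72 ± 0.27. CCNG1, a p53 target, was higher by 0.77 ± 0.18, the amino acid transporter SLC36A4 by 0.96 ± 0.21, PIGL, an enzyme of GPI anchor synthesis, by 0.88 ± 0.21 and ENY2 by 0.62 ± 0.15. The adenylyl cyclase ADCY4, which makes cyclic AMP, had 13.8 ± 2.17 CPM against 32.3 ± 5.77, a difference of -1.16 ± 0.20. The elastic-fibre protein FBLN5 differed by -0.92 ± 0.16, EXOC3L1 by -1.04 ± 0.23 and AKR1E2 by -0.85 ± 0.19. With each library's trend on GC content and transcript length removed, SLC36A4 was higher by 0.63 and ENY2 by 0.40. RBM3 lies on chromosome X from 48574449 to 48579066 and ADCY4 on chromosome 14 from 24318349 to 24335093, in GRCh38.

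All these genes missed the threshold: limma called 0 genes, with a smallest adjusted p of 0.866. An unadjusted p under 0.05 was found for 696 genes (330 higher, 366 lower), where chance alone gives 805. EdgeR called 0 genes (741 unadjusted), and DESeq2 called RBM3 higher and ADCY4 and FBLN5 lower (871 unadjusted), with adjusted p of 0.000221, 0.000571 and 0.00332. Over all alternatives the adjusted p ranged from 0.000221 to 0.999 for RBM3, from 0.000571 to 0.999 for ADCY4 and from 0.00332 to 0.999 for FBLN5. Groups did not overlap in 14.4% of genes, where chance gives 10%. The unadjusted count was 253 without space_microg replicate 3, 369 without space_microg replicate 2 and 464 without ground replicate 1, and 2032 without both libraries that stand apart.

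**Figure D3:**
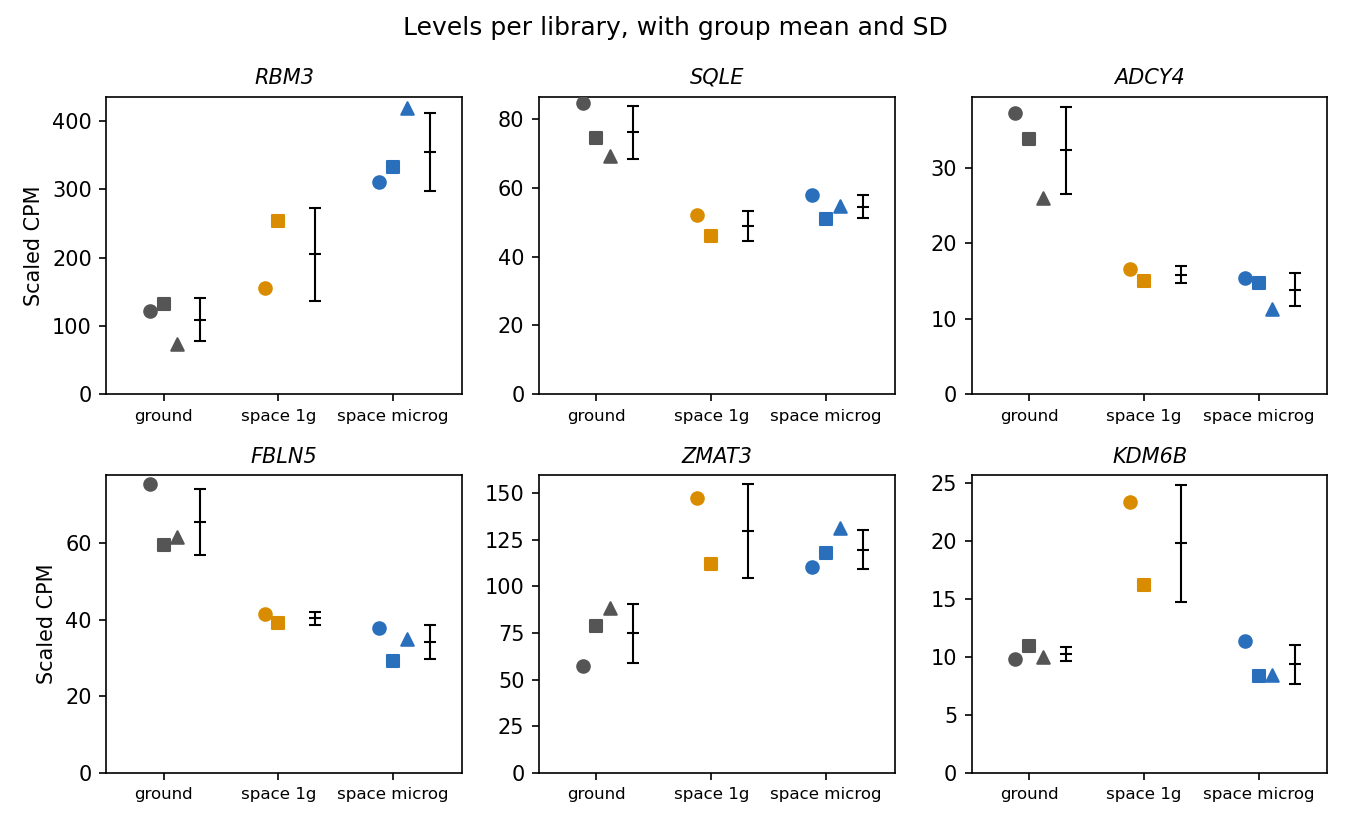
Scaled CPM of 6 genes per library, with bars for the group mean and SD, the colour giving the group and the marker the replicate (circle 1, square 2, triangle 3). RBM3 is between 156 and 418 CPM in the 5 flight libraries and between 73.5 and 132 on the ground, and SQLE between 45.9 and 57.8 against 69.2 to 84.6.

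Among gene lists, 8 rose and 8 fell in space_microg with the preset correlation, and each of the 16 calls was lost with an estimated one (adjusted p = 0.781 with an estimated correlation for mitosis, adjusted p = 0.759 for the other 15). The balance rests on single libraries, with 14 called higher and 6 lower without ground replicate 3 and 4 higher and 13 lower without ground replicate 2. It was 7 and 11 without space_microg replicate 1, 9 and 5 without space_microg replicate 2, and 6 and 11 without space_microg replicate 3. Genes of the cytosolic ribosome rose, with 75 of 76 members higher and a median of 0.50 (adjusted p = 3.63e-28), among them RPL27 by 0.81 ± 0.26 and RPL34 by 0.91 ± 0.30. The median was 0.29 without space_microg replicate 3, whose mean score of 0.71 was the highest of all libraries, and near-identical copies leave single ribosomal protein genes uncertain. Nuclear genes of oxidative phosphorylation rose with 63 of 70 members higher and a median of 0.27 (adjusted p = 1.51e-10), as in COX7C (0.68 ± 0.28), with a median of 0.10 without space_microg replicate 3 and 0.13 without ground replicate 2. Core histone genes rose with 34 of 34 members higher and a median of 0.71 (adjusted p = 1.27e-09), or 0.40 without ground replicate 3, and are uncertain as copies. Proteasome subunits rose (29 of 33 higher, median 0.17, adjusted p = 1.03e-05). The median was 0.10 without space_microg replicate 3, 0.29 without ground replicate 3 and 0.039 without ground replicate 2, which ended the call.

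Genes of endothelial identity fell in space_microg, with 25 of 32 members lower and a median of -0.37 (adjusted p = 9.16e-05; adjusted p = 0.759 with an estimated correlation). The angiopoietin receptor TEK differed by -0.63 ± 0.19 and the VEGF receptors KDR and FLT1 by -0.49 ± 0.20 and -1.09 ± 0.45. Without space_microg replicate 2, in which GC content and transcript length explained 54.5% of the deviation from the mean library against 2.82% to 21.8% elsewhere, the median was -0.21. Notch signalling, which patterns vessels, fell with 17 of 19 members lower and a median of -0.38 (adjusted p = 0.000671; adjusted p = 0.759 with an estimated correlation), with DLL4 at -0.82 ± 0.22 and JAG1 at -0.91 ± 0.33. Its median was -0.23 without space_microg replicate 2, -0.64 without ground replicate 2 and -0.21 without ground replicate 3. Heat shock genes, the chaperones of misfolded proteins, fell with 20 of 25 members lower and a median of -0.39 (adjusted p = 0.000117; adjusted p = 0.759 with an estimated correlation), among them HSPH1 at -0.66 ± 0.20 and HSPA1A at -1.23 ± 0.43, and with a median of -0.18 without ground replicate 3. Cholesterol synthesis genes fell with 20 of 25 members lower and a median of -0.18 (adjusted p = 0.000179; adjusted p = 0.759 with an estimated correlation), among them SQLE at -0.47 ± 0.14 and the transcription factor SREBF2, which switches on this pathway, at -0.38 ± 0.13. Its median was -0.28 without space_microg replicate 3 and -0.41 without ground replicate 3.

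The other 8 called lists each turned or lost the call without 1 or more single libraries (adjusted p = 0.781 with an estimated correlation for mitosis, adjusted p = 0.759 for the rest). Mitosis rose (40 of 43 higher, median 0.28, adjusted p = 0.00117), with 0.43 without ground replicate 1 and -0.015 without ground replicate 3. NRF2 and oxidative stress genes rose (30 of 35, median 0.13, adjusted p = 0.0017), with NQO1 at 0.45 ± 0.16. Its median became 0.26 without space_microg replicate 2. The call ended without space_microg replicate 3 (0.0049) or ground replicate 2 (0.073). Translation factors rose (25 of 34, median 0.12, adjusted p = 0.00601), with 0.071 without ground replicate 1 and 0.24 without ground replicate 3. The list was not called without ground replicate 2 (0.033). Actin cytoskeleton genes rose (32 of 46, median 0.11, adjusted p = 0.0329), with 0.20 without space_microg replicate 2. This call was lost without space_microg replicate 1 (0.054), space_microg replicate 3 (0.075) or ground replicate 2 (0.10). Immediate early genes fell (27 of 31 lower, median -0.29, adjusted p = 0.0127), with -0.51 without space_microg replicate 1, -0.64 without ground replicate 2, -0.18 and no call without space_microg replicate 2, and 0.040 without ground replicate 3. Matrix proteases and inhibitors fell (17 of 20, median -0.28, adjusted p = 0.0329), with TIMP3 at -0.93 ± 0.22 and a median of -0.50 without ground replicate 2. That call ended without space_microg replicate 2 (-0.19), ground replicate 1 (-0.33) or ground replicate 3 (-0.0034). Angiogenesis ligands and receptors fell (22 of 29, median -0.26, adjusted p = 0.0423), with -0.41 without space_microg replicate 1 and -0.42 without ground replicate 2. The list lost its call without space_microg replicate 2 (-0.16), ground replicate 1 (-0.38) or ground replicate 3 (-0.14). Extracellular matrix genes fell (26 of 43, median -0.054, adjusted p = 0.0423), with -0.12 without space_microg replicate 1, -0.19 without space_microg replicate 3, -0.19 without ground replicate 3 and 0.025 without space_microg replicate 2. No call was made without ground replicate 1 (-0.0044), ground replicate 2 (-0.052) or either space_1g library (-0.054 in both).

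Over all genes 0 members of any list passed in limma, and 3 passed adjusted over the list alone, 1 each in cholesterol synthesis, matrix proteases and extracellular matrix. Without space_1g replicate 1 and ground replicate 3, 21 lists were called, 12 of them among the 16 and in the same direction, and p53 targets, not called with all libraries (median 0.08, adjusted p = 0.0682), had a median of 0.71 (adjusted p = 1.44e-20; adjusted p = 0.620 with an estimated correlation). With an estimated correlation all 21 calls were lost, the smallest adjusted p being 0.620.

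Space_1g against ground asks what flight does at normal weight, with radiation, spinning in the centrifuge and the other conditions of flight. SQLE, an enzyme of cholesterol synthesis, had 49.0 ± 4.36 CPM in space_1g and 76.1 ± 7.79 on the ground, a difference of -0.62 ± 0.16, and SCD, which makes unsaturated fatty acids, differed by -0.86 ± 0.24. ADCY4 differed by -0.97 ± 0.23 and FBLN5 by -0.68 ± 0.18. The phosphatase PTP4A1 had 149.9 ± 16.5 CPM against 87.8 ± 8.60, higher by 0.76 ± 0.15, the sorting receptor SORL1 was higher by 0.85 ± 0.20, PIGL by 0.95 ± 0.23, the p53 target ZMAT3 by 0.79 ± 0.22 and the histone demethylase KDM6B by 0.87 ± 0.24. SQLE lies on chromosome 8 from 124998497 to 125022283 and PTP4A1 on chromosome 6 from 63521746 to 63583377.

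All these genes missed the threshold: limma called 0 genes (smallest adjusted p 1.00). At an unadjusted p under 0.05 it had 249 genes (116 higher, 133 lower), where chance gives 805. EdgeR called 0 (227 unadjusted) and DESeq2 0 (327 unadjusted). Groups did not overlap in 10.7% of genes, where chance gives 20%. The unadjusted count was 84 without ground replicate 1, 871 without space_1g replicate 2 and 1327 without ground replicate 3.

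Cholesterol synthesis genes fell in space_1g, with 22 of 25 members lower and a median of -0.35 (adjusted p = 5.6e-13; adjusted p = 0.586 with an estimated correlation). Examples are CYP51A1 at -0.46 ± 0.15 and MSMO1 at -0.66 ± 0.23, and 2 members passed adjusted over the list alone, against 0 over all genes. Endothelial identity genes fell with 29 of 32 members lower and a median of -0.36 (adjusted p = 9.55e-08; adjusted p = 0.765 with an estimated correlation), among them TEK at -0.54 ± 0.21 and the junction protein CDH5 at -0.58 ± 0.25, and with a median of -0.21 without space_1g replicate 2. No single library ended these calls.

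The p53 targets rose, with 29 of 30 members higher and a median of 0.50 (adjusted p = 6.74e-07; adjusted p = 0.867 with an estimated correlation), among them CCNG1 at 0.46 ± 0.20. The median was -0.23 without space_1g replicate 1, 1.25 without space_1g replicate 2 and 0.97 without ground replicate 3, and 0.31 and 0.26 without ground replicates 1 and 2. Without both libraries that stand apart it was 0.37 (adjusted p = 7.87e-07; adjusted p = 0.846 with an estimated correlation). Genes of the integrated stress response, set off by amino acid shortage and unfolded proteins, rose with 28 of 30 members higher and a median of 0.31 (adjusted p = 0.00203; adjusted p = 0.867 with an estimated correlation), as in SLC7A11 (0.88 ± 0.44). That median was -0.20 without space_1g replicate 1, 0.93 without space_1g replicate 2 and 0.96 without ground replicate 3. The call ended without ground replicate 1 (0.095) or ground replicate 2 (0.011), and also with 1 surrogate variable. Without both libraries that stand apart the median was 0.35 (adjusted p = 1.07e-07; adjusted p = 0.846 with an estimated correlation). Core histone genes fell with 33 of 34 members lower and a median of -0.50 (adjusted p = 1.28e-05; adjusted p = 0.867 with an estimated correlation), but were called higher at 0.59 without space_1g replicate 1, and had -1.55 without space_1g replicate 2, -0.22 without ground replicate 1 and -0.89 without ground replicate 3. Mitosis fell with 41 of 43 members lower and a median of -0.29 (adjusted p = 1.28e-05; adjusted p = 0.867 with an estimated correlation), but was called higher at 0.33 without space_1g replicate 1, with -0.87 without space_1g replicate 2, -0.18 without ground replicate 2 and -0.56 without ground replicate 3. The list was not called without ground replicate 1 (-0.12). Extracellular matrix genes fell (34 of 43 lower, median -0.28, adjusted p = 0.000206; adjusted p = 0.856 with an estimated correlation), with 0.049 without space_1g replicate 1 and -0.45 without space_1g replicate 2.

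Heat shock genes fell (18 of 25 lower, median -0.26, adjusted p = 2.63e-05; adjusted p = 0.856 with an estimated correlation), with HSPH1 at -0.58 ± 0.22 and a median of -0.42 without ground replicate 2. This call was lost without space_1g replicate 2 (-0.23) or ground replicate 3 (-0.20). NRF2 genes rose (26 of 35, median 0.16, adjusted p = 0.00389; adjusted p = 0.856 with an estimated correlation). That call ended without space_1g replicate 2 (0.13) or ground replicate 2 (0.075). Endoplasmic reticulum chaperones fell (16 of 24, median -0.11, adjusted p = 0.00409; adjusted p = 0.867 with an estimated correlation), with -0.17 without space_1g replicate 1 and -0.30 without ground replicate 2. The list lost its call without space_1g replicate 2 (-0.11) or ground replicate 3 (-0.044). DNA replication genes fell (33 of 44, median -0.11, adjusted p = 0.00554; adjusted p = 0.765 with an estimated correlation). No call was made without space_1g replicate 1 (-0.060) or ground replicate 3 (-0.079). Fatty acid metabolism fell (19 of 28, median -0.13, adjusted p = 0.0148; adjusted p = 0.586 with an estimated correlation), with -0.084 without ground replicate 2. The call ended without space_1g replicate 1 (-0.060) or ground replicate 3 (-0.10). Junction genes fell (23 of 31, median -0.11, adjusted p = 0.0173; adjusted p = 0.765 with an estimated correlation). The list was not called without space_1g replicate 1 (-0.11), space_1g replicate 2 (-0.19) or ground replicate 3 (-0.13). Lysosome genes fell (36 of 50, median -0.090, adjusted p = 0.0206; adjusted p = 0.867 with an estimated correlation), with -0.14 without either ground replicate 1 or 2. This call was lost without space_1g replicate 1 (-0.11), space_1g replicate 2 (-0.050) or ground replicate 3 (0.0024). Proteasome subunits rose (25 of 33, median 0.078, adjusted p = 0.0322; adjusted p = 0.877 with an estimated correlation), with 0.22 without ground replicate 3 and -0.049 without ground replicate 2. That call ended without space_1g replicate 1 (0.079) or space_1g replicate 2 (0.072). DNA repair fell (43 of 60, median -0.078, adjusted p = 0.0481; adjusted p = 0.867 with an estimated correlation), with 0.0086 without space_1g replicate 1 and -0.14 without space_1g replicate 2. The list lost its call without ground replicate 2 (-0.031) or ground replicate 3 (-0.13). It was also not called with a pseudocount of 4, quantile scaling, 1 surrogate variable or the GC and length trend removed. Without both libraries that stand apart, 17 lists were called, 7 of them among the 16 in the same direction and 1, core histones, in the opposite, and all 17 calls were lost with an estimated correlation (smallest adjusted p = 0.846). With all libraries 4 lists were called higher and 12 lower, against 1 and 17 without ground replicate 2, 12 and 5 without ground replicate 3, 6 and 9 without space_1g replicate 2, 9 and 8 without both libraries that stand apart, and 11 and 8 with the replicate number as a block.

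Space_microg against space_1g asks how weightlessness differs from 1 g in the centrifuge, since both groups flew. Any effect of the spinning itself cannot be separated from that of weight. KDM6B had 9.36 ± 1.72 CPM in space_microg and 19.8 ± 5.02 in space_1g, a difference of -1.0 ± 0.24. POLR2A, the catalytic subunit of RNA polymerase II, had 300.1 ± 28.9 against 493.7 ± 16.0, a difference of -0.72 ± 0.20, and the immediate early gene FOS differed by -0.82 ± 0.26, TONSL by -0.59 ± 0.18 and RN7SL5P by -0.96 ± 0.29. Retinaldehyde dehydrogenase ALDH1A1 was higher by 0.78 ± 0.24, DBI, a carrier of acyl-CoA, by 0.83 ± 0.26, RPL22L1 by 0.76 ± 0.24, the histone gene HIST4H4 by 1.36 ± 0.41 and SNORD114-20 by 1.24 ± 0.36. The values of RN7SL5P, HIST4H4 and SNORD114-20 are uncertain, since reads of near-identical copies or of a host intron can fall on them. Without space_1g replicate 1 the differences shrank to 0.72 for HIST4H4, 0.66 for SNORD114-20, 0.49 for ALDH1A1 and -0.47 for FOS. With the GC and length trend removed, KDM6B differed by -0.60 and TONSL by -0.15. KDM6B lies on chromosome 17 from 7839904 to 7854796.

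All 10 genes missed the threshold: limma called 0 genes (smallest adjusted p 0.912). At an unadjusted p under 0.05 there were 212 (112 higher, 100 lower), where chance gives 805. EdgeR called 0 (221 unadjusted) and DESeq2 0 (339 unadjusted). Groups did not overlap in 14.2% of genes, where chance gives 20%. The unadjusted count was 33 without space_1g replicate 1, 71 without space_microg replicate 3, 117 without space_microg replicate 2, 139 without ground replicate 1, 496 without ground replicate 3 and 2421 without space_1g replicate 2.

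Of the lists, 6 rose and 2 fell in space_microg, each with an adjusted p = 0.838 with an estimated correlation. Core histone genes rose with 34 of 34 members higher and a median of 1.24 (adjusted p = 1.21e-21), 0.12 without space_1g replicate 1, whose histone score was -1.72, and 2.35 without space_1g replicate 2. Cytosolic ribosome genes rose with 73 of 76 members higher and a median of 0.42 (adjusted p = 1.71e-21), among them RPS12 at 0.71 ± 0.24, with medians of 0.23 without space_microg replicate 3, 0.16 without space_1g replicate 1 and 0.65 without space_1g replicate 2. Oxidative phosphorylation genes rose (59 of 70 higher, median 0.19, adjusted p = 2.52e-08), with COX7C at 0.82 ± 0.31. That median was 0.30 without space_microg replicate 1, 0.30 without space_microg replicate 2, 0.079 without space_1g replicate 1 and 0.29 without space_1g replicate 2. No call was made without space_microg replicate 3 (0.053). Mitosis rose (42 of 43, median 0.56, adjusted p = 7.11e-13), with NDC80 at 0.64 ± 0.28 and medians of -0.052 without space_1g replicate 1 and 1.16 without space_1g replicate 2. Proteasome subunits rose (24 of 33, median 0.094, adjusted p = 0.0309), with 0.14 without space_microg replicate 1 and 0.16 without space_microg replicate 2. The call ended without space_microg replicate 3 (0.025) or space_1g replicate 2 (0.10). Cholesterol synthesis rose (17 of 25, median 0.14, adjusted p = 0.0485). The list was not called without space_microg replicate 1 (0.15), space_microg replicate 3 (0.15), space_1g replicate 2 (0.099) or ground replicate 2 (0.14).

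Immediate early genes, switched on within minutes of a stimulus, fell in space_microg against space_1g with 28 of 31 members lower and a median of -0.65 (adjusted p = 6.04e-05; adjusted p = 0.838 with an estimated correlation), among them FOSB at -1.02 ± 0.34. Its median stood at -0.36 without space_microg replicate 2, 0.11 without space_1g replicate 1 and -1.17 without space_1g replicate 2. The call also ended with 1 surrogate variable. Integrated stress response genes fell with 30 of 30 members lower and a median of -0.46 (adjusted p = 0.000512; adjusted p = 0.838 with an estimated correlation), with 0.076 without space_1g replicate 1 and -1.0 without space_1g replicate 2. Over all genes and adjusted over the list alone, 0 members passed in limma, where 212 genes had an unadjusted p under 0.05. The lists called higher and lower numbered 12 and 4 without space_1g replicate 1, 5 and 7 without space_1g replicate 2, 5 and 6 without space_microg replicate 1, 9 and 2 without space_microg replicate 2, 4 and 3 without space_microg replicate 3, and 6 and 7 without ground replicate 3. Without both libraries that stand apart, 17 lists were called, 5 of them among the 8 and in the same direction, and all 17 calls were lost with an estimated correlation (smallest adjusted p = 0.834).

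Whether weightlessness and the other conditions of flight push the same genes the same way was examined with both steps, ground to space_1g and space_1g to space_microg. RBM3 was higher in each step, by 0.90 ± 0.30 and 0.82 ± 0.30. Collagen gene COL6A3 differed by -0.65 ± 0.52 and -0.70 ± 0.52, and the chaperone HSPA1A by -0.77 ± 0.48 and -0.46 ± 0.48. Without both libraries that stand apart the second step was 0.47 for RBM3, -0.011 for COL6A3 and -0.049 for HSPA1A, so the second step of COL6A3 and HSPA1A rests on space_1g replicate 1. Among genes with opposite steps, the anchoring collagen COL7A1 differed by 1.42 ± 1.54 and -1.99 ± 1.54, with 536.5 CPM in space_1g replicate 1, 345.5 in ground replicate 3 and 13.4 to 100.2 in the other 6 libraries. PDK4, a kinase that slows glucose oxidation, differed by -1.47 ± 0.96 and 1.20 ± 0.96, with 14.4 and 20.4 CPM in these libraries and 60.8 to 196 in the others. Without both libraries the second step was 0.012 for COL7A1 and 0.091 for PDK4. In limma 0 genes passed in both steps; at an unadjusted p under 0.05, 1 gene passed both in the same direction and 25 in opposite directions.

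Both steps share the space_1g libraries with opposite sign, which by itself makes opposite directions. Across genes, which are not independent replicates, the correlation of the steps was -0.545, against -0.601 in 100 simulations of unchanged groups, and the covariance -0.0510 against -0.0688. The correlation was -0.424 without both libraries that stand apart, against -0.707 in simulations of that fit. Simulated genes varied independently, unlike those of the real libraries, so a distance from the simulated value is no sign of a change. Over 100 regroupings of all libraries the correlation ran from -0.976 to 0.166, with a median of -0.706. The number of genes with opposite directions in these regroupings had a median of 54 and a maximum of 5300. Of the 5 lists called in both steps, mitosis, core histones, the integrated stress response and cholesterol synthesis went in opposite directions and the proteasome in the same, all with adjusted p = 0.586 or more with an estimated correlation. Without space_1g replicate 1, which leaves that group with 1 library, the steps of mitosis were 0.33 and -0.052. Those of core histones were 0.59 and 0.12, so this list then went in the same direction. The integrated stress response had -0.20 and 0.076, and cholesterol synthesis -0.35 and 0.12. Without ground replicate 3 as well, the first step of the integrated stress response was 0.35 (adjusted p = 1.07e-07; adjusted p = 0.846 with an estimated correlation) and its second 0.076, not called.

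The overlap of both flight groups against ground asks what flight does with and without artificial gravity. ADCY4 and FBLN5 were among the 5 lower genes with the smallest p in both comparisons, and PIGL among the higher. At an unadjusted p under 0.05, 98 genes passed in both comparisons in the same direction and 0 in opposite directions, where independent lists give 5.40 and 5.36 and regroupings a median of 30.5 in the same direction, with a maximum of 2951. In limma 0 genes passed the threshold in both. The correlation across genes was 0.274, against 0.446 in simulations of unchanged groups that share the ground libraries and -0.457 to 0.923 over the regroupings. It was 0.766 without both libraries that stand apart, against 0.447 in simulations of that fit, so its side of the value for unchanged groups depends on these libraries. Of 8 lists called in both, 6 went in the same direction: cholesterol synthesis, endothelial identity, heat shock and extracellular matrix fell, and NRF2 genes and the proteasome rose, while mitosis and core histones went in opposite directions. All 8 lost the call with an estimated correlation, with adjusted p = 0.759 or more in space_microg and adjusted p = 0.586 or more in space_1g. Part of any overlap comes from the shared ground libraries, which are too few to divide between the comparisons.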

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

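The fits with 1 surrogate variable, with edgeR or DESeq2, without both libraries that stand apart and with the GC and length trend removed were chosen after seeing the data. Where a value changed, the cause was not tested unless given. All 690 values of the genes named for the smallest p in a comparison, over the alternatives, kept their direction. Their groups do not overlap by the naming rule, so leaving out a library or changing the pseudocount could not turn them. Genes named for the joint directions were not counted here, and some reversed without both libraries that stand apart. The counted genes passed the threshold in 10 values with array weights, 3 with DESeq2 and 1 with the surrogate variable. In space_microg against ground, array weights called 260 genes higher and 355 lower, with a weight of 43.4 on ground replicate 1 and 0.182 to 1.79 on the others. The surrogate variable called 1 higher, and DESeq2 1 higher and 2 lower. Of 720 list values, 533 kept direction and call, 162 lost the call and 25 reversed. An estimated correlation and fry each called 0 lists in every comparison, with smallest adjusted p of 0.759, 0.586 and 0.838 and of 0.773, 0.700 and 0.902. In limma 696, 249 and 212 genes had an unadjusted p under 0.05. Space_microg against space_1g had 13 lists called higher and 4 lower without both libraries that stand apart, 17 and 0 with the surrogate variable, 6 and 7 with the GC and length trend removed and 4 and 9 with the replicate number as a block. It had 7 to 16 called lists with single libraries left out. Without both libraries that stand apart, the medians reversed to -0.015 (mitosis) and 0.040 (immediate early genes) in space_microg against ground, to 0.032 (mitosis) and 0.26 (core histones) in space_1g against ground, and to -0.052 (mitosis), 0.076 (integrated stress response) and 0.11 (immediate early genes) in space_microg against space_1g. The surrogate variable reversed the integrated stress response to 0.11 there, and removal of the GC and length trend reversed extracellular matrix to 0.098 in space_microg against ground. In that comparison the surrogate variable ended the calls of mitosis, immediate early genes, matrix proteases and angiogenesis ligands and receptors. In space_1g against ground it ended those of the integrated stress response, the proteasome and DNA repair. In space_microg against space_1g it ended that of immediate early genes. The replicate block ended the calls of DNA replication (-0.084), junctions (-0.13), endoplasmic reticulum chaperones (-0.049) and fatty acid metabolism (-0.11) in space_1g against ground. It reversed lysosome to 0.0061 there. In space_microg against space_1g it ended the calls of oxidative phosphorylation and cholesterol synthesis and reversed proteasome to -0.019. With the block 0 genes were called in each comparison (limma, 1013, 759 and 850 unadjusted). Whether replicate numbers mark pairs was not settled. By deviations from the group means, 3 of 8 libraries were closest to a library of the same number. The paired deviations correlated across genes between -0.68 and 0.68. The libraries that stand apart weigh heavily in these deviations, and both space_1g deviations mirror each other, so the check can neither show nor exclude pairs. With single libraries left out, medians in space_microg against ground ran from -0.015 to 0.43 for mitosis, -0.19 to 0.025 for extracellular matrix and -0.64 to 0.040 for immediate early genes. In space_1g against ground they ran from -0.14 to 0.0024 for lysosome, -0.23 to 1.25 for p53 targets, -0.14 to 0.0086 for DNA repair, -0.87 to 0.33 for mitosis, -1.55 to 0.59 for core histones, -0.45 to 0.049 for extracellular matrix, -0.20 to 0.96 for the integrated stress response and -0.049 to 0.22 for the proteasome. In space_microg against space_1g they ran from -0.052 to 1.16 for mitosis, -1.0 to 0.076 for the integrated stress response and -1.17 to 0.11 for immediate early genes. Depth limits low genes: 3 reads are 0.0855 to 0.12 CPM.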

Other observations

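Tests chosen after the result was seen are those of epithelial cells, of culture temperature, of the cholesterol list without both libraries that stand apart, and the comparison of all 5 flight with all 3 ground libraries for the cholesterol list. The tests of library depth, of GC content and transcript length and of sterol in the cells likewise address patterns already seen in these libraries. The single libraries and genes described next were also singled out after their values were seen.

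In space_1g replicate 1 and ground replicate 3, several genes lay far above or below the other libraries. The chemokine CCL5 had 71.6 and 33.7 CPM against 1.04 to 9.86, and the small GTPase RRAD, a p53 target, 119 and 109.9 against 2.23 to 19.6. FLG, the skin-barrier protein filaggrin, had 55.7 and 32.5 CPM against 0.239 to 7.32. The NF-kB and inflammation list, genes of the main inflammatory transcription factor, had mean scores of 0.84 and 1.02 against -0.55 to -0.06, and the senescence secretory list 0.54 and 0.66 against -0.56 to 0.22. CLEC3B had 0.975 and 0.705 CPM against 8.43 to 36.2.

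Autophagy machinery, which digests cell contents, was called in no comparison, with medians of 0.035, 0.0025 and 0.052 over 41 members (adjusted p = 0.402, 0.984 and 0.486). In space_1g against ground its median and mean were above 0 and its test below. The interferon response list was not called either, with medians of -0.27, 0.12 and -0.50, but without both libraries that stand apart its medians were 0.57, -0.24 and 0.84, each called with the preset correlation and with adjusted p = 0.776, 0.846 and 0.834 with an estimated correlation. Of the 47 lists, 23 were called in no comparison, among them focal adhesion, YAP and TAZ targets, shear stress response, hypoxia response, glycolysis and circadian clock.

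The first pattern is that space_1g replicate 1 and ground replicate 3 stand apart on the first component. Their read totals, 30929975 and 34625881, lay within the 24248964 to 35388757 of the other libraries, so depth is not the whole cause. Thinning all libraries to the smallest read total left 100.2% of the gap to the nearest other library. The values were already scaled to depth, so thinning could change little and adds little here. Removing each library's trend on GC content and transcript length, known for 86.1% of genes, left 88.5%, so that trend is not the whole cause either. Epithelial cells mixed in remain open: the lower of the median scores of the epithelial list, of which 8 of 16 markers were measured, was 0.15, above 0 but short of the 0.5 set for it. KRT7 had 369 and 428 CPM against 77.8 to 215 and KRT17 8.39 and 8.03 against 0.159 to 2.93, while KRT18 did not stand out (228 and 317 against 225 to 333) and CLDN7 was lower than in all others (2.76 and 3.59 against 3.86 to 10.0). A wrong label, or a difference in fixation or storage, was not tested and stays open, as does any biological explanation, since no group of the labels holds these libraries and no other.

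The second pattern is RBM3, higher in all 5 flight libraries than in all 3 on the ground by a mean of 1.40, with no test of it given because it was picked for this in the same libraries. After removal of the GC and length trend, RBM3 was still higher by 1.63 in space_microg, which argues against that trend as the whole cause. A lower culture temperature in flight is a candidate explanation that these data do not decide. The cold-induced gene CIRBP was higher in flight by 0.21 (exact permutation p = 0.107, 0.161 adjusted over 6 tests) and the heat shock list lower by a difference of -0.31 (exact permutation p = 0.232, adjusted 0.279), both on the side a lower temperature predicts and neither past the threshold. An effect of flight itself stays open and cannot be separated from temperature here.

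The third pattern is the lower level of cholesterol synthesis genes in both flight groups. Without both libraries that stand apart, the medians stayed below 0, at -0.41 in space_microg and -0.39 in space_1g. That fit leaves space_1g with 1 library, so its value there rests on a single flight library. After removal of the GC and length trend, with all libraries, the medians were -0.24 (adjusted p = 1.64e-05) and -0.34 (adjusted p = 1.31e-11). Both calls were made with the preset correlation. An estimated one was not run after removal of the trend, and before its removal it called 0 lists. More sterol in the cells may lower these genes. The 5 targets of the sterol-sensing LXR receptors differed by a mean of 0.017 (exact permutation p = 0.946), which leaves this undecided. They went both ways, with ABCA1 at 0.38, ABCG1 at 0.013, MYLIP at -0.16, LPCAT3 at -0.12 and SMPDL3A at -0.029. ABCA1 had 112.9 and 86.0 CPM in space_1g replicate 1 and ground replicate 3, against 14.1 to 46.3 elsewhere. These targets were not tested without both libraries. Over all 5 flight and 3 ground libraries the list score differed by -0.30 (exact permutation p = 0.0536, two-sided, 0.107 adjusted over 6 tests).

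The 6 libraries of space_microg and ground make 10 splits, too few for a share under 0.05: the real split gave 0 genes past the threshold in limma and the highest other 0 (10 splits as large). Counts of splits as large, here and below, include the real split itself. It gave 696 genes at an unadjusted p under 0.05 and the highest other 2018 (2 as large), and 16 lists and the highest other 24 (9 as large). The 8 libraries make 56 splits of 5 against 3. The real split of flight against ground gave 608 genes at an unadjusted p under 0.05, with 24 splits as large and 5611 in the highest other, and 17 lists, with 26 splits as large and 27 in the highest other, so chance cannot be excluded for either. The split with 5611 genes, 2785 of them past the threshold, sets apart space_microg replicate 1, space_1g replicate 1 and ground replicate 3, the highest on the first component (1.51, 60.7 and 64.7). It points to the structure of the samples already described and is no separate support for it.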
